A study of Mus musculus with 7 samples.

How the data were processed

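Chromatin immunoprecipitation and sequencing (ChIP-seq) was done on globose basal cells of the mouse olfactory epithelium for H3K27me3 (2 libraries) and H3K27ac (2 libraries), with 3 input libraries. Per the labels' protocols, the cells came from adult wild-type mice 7 to 10 days after a methimazole lesion, cells of 3 mice were pooled for each replicate, and globose basal cells were taken from the suspension by magnetic selection with an antibody to c-Kit. Groups and replicate numbers were taken from the sample titles. The analysis used 4 peak lists, 1 for each immunoprecipitated library, and no peak list of an input library was used here. Replicates of a mark are taken to be separate pools of mice. By the labels, H3K27me3 replicate 1 and H3K27ac replicate 2 share an input, so equal replicate numbers do not pair the libraries. Whether these libraries came from the same pool of mice is not stated in the labels.

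Per the submitters' processing notes, the tools were fastp, Bowtie, Picard and MACS2 and the genome build was GRCm38 (mm10), with versions not given in the sources used here. The lists have 9 columns and no header, in the broad-peak layout of MACS2, and the authors called peaks for each library separately. In each list the authors deposited a fold enrichment of each peak over its background, a linear ratio averaged over the broad region. They also deposited a −log10 p and a −log10 q for each peak, and a score that equals 10 times the −log10 q cut to a whole number in at least 99.9% of rows. The smallest −log10 q lay just above 1 in each list, which corresponds to a q threshold of 0.1. These values are the authors' own for each peak and were used only to describe, rank and filter peaks within a list. The files used here give no read totals, so the depth of each library is unknown, and no interval or detection limit that needs read counts is given. The −log10 q grows with depth, so the number of peaks past a threshold depends on it, and a gene without a peak had none at this threshold and this unknown depth.

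Genes came from a RefSeq table of GRCm38.p6 that lists 49993 genes, of which 21883 protein-coding genes on chromosomes 1 to 19, X and Y were tested. The table gives gene coordinates without strand, and no genome sequence was used. The plan had called for promoters at gene starts. In their place a gene was counted as carrying a mark when peaks of both libraries of that mark overlapped, by at least 1 bp, a window of 1 kb on each side of either annotated gene end. Such a window can hold the promoter of a neighbouring gene, and it misses a promoter inside the gene. For the same reason peak length was divided among gene boundaries, gene bodies and intergenic sequence, not among exons and introns. Matching on CpG content was not possible without sequence, and random lists were matched on 10 classes of gene length instead. Transcript starts were not used here.

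Consensus regions of a mark were the bases covered in both of its libraries. Overlaps were compared with 1000 circular rotations of a list within each chromosome (200 for the distribution over genes and for the alternatives), over the 2693.2 Mb spanned by the lists and the gene table on 21 chromosomes. The permutation p is one-sided between replicates and for the distribution, and two-sided between marks. The smallest p that 1000 rotations can give is 0.001 one-sided and 0.002 two-sided, and 200 rotations can give 0.005 one-sided. Rotation does not keep gene density or mappability, so it tests against random placement only. Fisher's exact test, two-sided, compared the marks across genes and compared each of 33 gene lists (18 lists of symbols and 15 symbol patterns) with all other genes. Its p-values were adjusted by the Benjamini-Hochberg method over 66 tests of lists and marks, with a threshold of 0.05. Genes are not replicates, and neighbouring genes share peaks, so these p-values describe the libraries and are too small for clustered families. The share of a list was also placed among 10000 random lists of the same size. Whether a list differed between the marks was tested by Fisher's exact test on genes with exactly 1 of the marks, adjusted over the 33 lists. H3K27me3 consensus regions were merged across gaps of up to 3 kb and H3K27ac consensus regions were stitched across gaps of up to 12 kb.

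The lists of cell type markers, complexes and gene families and the rule for naming genes were fixed before the data were examined. Named genes are the 12 genes per mark with the best mean rank of fold enrichment over the libraries of that mark, without predicted genes (symbols of Gm and digits or ending in Rik, so that a LOC locus could be named), and the 8 best-ranked genes with both marks. They also include genes at the ends of the 10 longest regions of each mark (at most 4 per region), and up to 4 genes from each list that carried H3K27me3, 4 that carried H3K27ac and 4 with neither, in the order of the list. Every member of the globose basal cell and Polycomb lists could be named. A few genes that this rule names are not reported here. The lists cover globose basal cells and neuronal progenitors, immature and mature olfactory neurons, horizontal basal cells, sustentacular cells, Bowman's glands, respiratory epithelium, microvillar and tuft cells, mast cells, melanocytes, leukocytes, stroma and endothelium, olfactory ensheathing glia, lineage regulators of other tissues, Polycomb subunits and H3K27 demethylases, proliferation, cyclin-dependent kinase inhibitors and housekeeping genes. By symbol pattern they cover the Hox, Sox, Pax, Fox, Tbx, Nkx and Lhx families, Wnt, Bmp and Fgf ligands, keratins, ribosomal proteins, olfactory and vomeronasal receptors and Zfp zinc finger genes. The ribosomal pattern also takes 10 ribosomal protein S6 kinase genes.

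The alternatives were a −log10 q of at least 5, windows of 500 bp and 2.5 kb, at least 500 bp covered, peaks of at least 500 bp, an overlap of at least 50% of the shorter peak, autosomes only, a mark in either replicate, the libraries that share an input, merging gaps of 1 kb and 10 kb, and leaving out each library in turn. Windows over the whole gene, a −log10 q of at least 2, leaving out the chemosensory receptor genes and requiring both marks on a shared base were added after the data were seen, as were leaving out a library for the distribution over genes and the longest regions, and the groups by the first 3 letters of gene symbols. Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on simulated data and equalled a base-by-base count in 50 of 50 simulated sets. For the overlap of the marks, 1 of 40 randomly rotated lists gave a p under 0.05, and 92.4% of a planted shared length was recovered above the rotations. For the gene lists, tested on 21883 genes, 9 of 10 planted lists with 90% of members marked were called, and 0 of 33 lists without a planted change were called. Each simulated gene was marked independently of its neighbours, so this test does not cover false calls in clustered families whose genes share peaks.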

Results

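Globose basal cells (GBCs) are the dividing progenitors at the base of the olfactory epithelium, and they rebuild its neurons and supporting cells after injury. The series profiled 2 modifications of the same histone residue in these cells by ChIP-seq. H3K27me3 is the repressive mark written by Polycomb Repressive Complex 2, and H3K27ac marks active promoters and enhancers. Cells were taken from adult wild-type mice 7 to 10 days after a lesion with methimazole, a drug that strips the olfactory epithelium, and were enriched by selection for the receptor c-Kit. Each mark had 2 libraries, each from a pool of 3 mice, and there was no untreated group, so the design compares the marks with each other and their positions with the genes. H3K27me3 replicates 1 and 2 gave 95749 and 65172 peaks that covered 3.75% and 3.36% of the genome span, and H3K27ac replicates 1 and 2 gave 77680 and 64279 peaks that covered 4.13% and 3.20%. Median fold enrichment was 3.46 and 3.21 for H3K27me3 and 3.61 and 3.43 for H3K27ac. The read depth is unknown. Few H3K27me3 peaks had a high significance, with 5.89% and 2.34% of peaks at a −log10 q of at least 5 against 31.1% and 18.8% of H3K27ac peaks.

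The first question was which genes lay under the repressive mark. H3K27me3 covered regulators of other tissues and whole families of patterning genes. All 39 genes of the Hox clusters, which set position along the body axis, carried it in both libraries, as did 14 of 14 Nkx, 8 of 8 Lhx and 9 of 9 Pax transcription factor genes and 19 of 19 Wnt ligand genes. Of the 28 lineage regulators of other tissues, 27 carried it, among them Gata4 and Nkx2-5 of the heart and Tbx5 of the forelimb and heart. The muscle regulator Myf5 was the exception, with a peak in replicate 1 only (fold enrichment 3.04). In each of these 6 lists the other genes carried H3K27me3 at a share of 28.5% to 28.6%. The lineage regulator list shares members with the Nkx, Pax and Lhx lists, Nkx2-5 among them, so the 6 lists are not independent. By Fisher's exact test the adjusted p was 8.45e-21 for the Hox genes, 3.62e-13 for the lineage regulators, 3.19e-10 for the Wnt ligands and 1.19e-07 for the Nkx genes, with 4.79e-05 for the Pax and 0.000143 for the Lhx genes. Fold enrichment at Gata4 was 10.1 and 7.10 in replicates 1 and 2, and at Nkx2-5 it was 11.9 and 7.89.

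Among the 12 genes with the strongest H3K27me3 peaks were Foxd1, Otp, Sp9, Igf2bp1, Egr4, Aldh1a2, Hoxa3, Hoxd10 and Pax5. Fold enrichment in these 12 genes ran from 14.7 at Pax5 to 18.6 at Egr4 in replicate 1 and from 9.17 at Aldh1a2 to 11.8 at Foxd1 in replicate 2. Aldh1a2 encodes an enzyme that makes retinoic acid, and Igf2bp1 binds RNA. Foxd1, Egr4 and Aldh1a2 also carried H3K27ac, at a low fold enrichment of 2.99 to 3.21. Other families were also over-represented, with 32 of 44 Fox genes (adjusted p = 9.84e-09), 19 of 22 Fgf ligands (adjusted p = 1.27e-07), 15 of 19 Sox genes (adjusted p = 3.11e-05), 11 of 13 Tbx genes (adjusted p = 0.000143) and 9 of 11 Bmp ligands (adjusted p = 0.00101), all by Fisher's exact test. The Bmp call ended without H3K27me3 replicate 2 (adjusted p = 0.0579 by the exact test) and in either replicate (0.0741), within a range of 0.000230 to 0.0741 over the alternatives. Because neighbouring genes such as Hoxd10 and Hoxd11 shared a peak, the genes of a cluster did not count independently.

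H3K27ac was frequent at proliferation, ribosomal protein and zinc finger genes, among other groups. All 12 proliferation genes carried it, among them Mki67, Top2a and the cyclin genes Ccnb1 and Ccna2, against 60.8% of the other genes (Fisher's exact test, adjusted p = 0.0108), and 2, Ccnd1 and Ccnd2, also carried H3K27me3 (adjusted p = 0.622). H3K27ac was also found at 89 of 97 genes of the ribosomal protein pattern (adjusted p = 5.47e-11, exact test), including Rpl31 at a fold enrichment of 10.4 and 8.86, and at 316 of 397 Zfp zinc finger genes (adjusted p = 9.54e-15, exact test). Both groups were under-represented under H3K27me3, which 6 of the 97 ribosomal pattern genes (adjusted p = 2.07e-07) and 60 of the 397 Zfp genes (adjusted p = 1.45e-09) carried by the exact test. Replicate 1 alone had H3K27me3 peaks at 29 and 129 of these genes, and the exact test still passed (adjusted p = 0.00277 and 8.46e-08, ranges over the alternatives 1.04e-10 to 0.0524 and 3.03e-15 to 0.000259). Of 12 housekeeping genes, 11 carried H3K27ac and 1, Pgk1, carried H3K27me3, neither of which passed the exact test (adjusted p = 0.0668 and 0.298), although the H3K27ac share passed in 5 of 11 alternatives (0.0242 to 0.140). With peaks at a −log10 q of at least 5 only, 7 of the 12 proliferation genes carried H3K27ac (adjusted p = 0.507 by the exact test, range over the alternatives 0.00441 to 0.507), and the H3K27me3 call on the ribosomal pattern had an adjusted p of 0.0524.

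Among the 12 genes with the strongest H3K27ac peaks were Cdc42, Ptp4a1, Wac, Kmt2e, Pex7, Sp3, Scaf8, Zfand5 and LOC115489044, a locus that overlaps Zfand5 and shares its peak. Cdc42, a small GTPase of the cytoskeleton, stood at a fold enrichment of 38.2 and 22.8 in replicates 1 and 2, and Kmt2e, which encodes a SET-domain protein, at 28.6 and 26.2. None of the 12 carried H3K27me3 in both libraries. H3K27ac was under-represented at the Hox genes (1 of 39, Hoxd8, adjusted p = 7.43e-14), the Nkx genes (1 of 14, Nkx2-6, adjusted p = 0.000143), the Lhx genes (1 of 8, Lhx2, adjusted p = 0.0158) and the lineage regulators of other tissues (8 of 28, adjusted p = 0.00172), all by Fisher's exact test. For the Sox (15 of 19), Pax (4 of 9), Fox (30 of 44) and Tbx (5 of 13) genes and the Wnt (9 of 19), Bmp (5 of 11) and Fgf (10 of 22) ligands the H3K27ac share did not pass, with adjusted p-values of 0.245 to 0.461 by the exact test. A low H3K27ac share passed in 2 of 11 alternatives for the Wnt ligands (lowest adjusted p = 5.98e-05, exact test), in 2 for the Fgf ligands (0.00544) and in 1 for the Bmp ligands (0.00375). In replicates 1 and 2 taken alone, H3K27ac peaks were found at 5 and 3 of 39 Hox genes, and at 4 and 3 of 14 Nkx genes, and these calls remained. The Nkx call ended when a peak in either replicate was enough (6 of 14, adjusted p = 0.161, exact test, range over the alternatives 3.68e-05 to 0.161). The call on the Lhx genes ended under 4 of 11 alternatives, with an adjusted p of up to 0.222 by the exact test when a peak in either replicate was enough.

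The series title asks about Polycomb Repressive Complex 2, whose own genes were acetylated. All 20 genes of the list of Polycomb subunits and H3K27 demethylases carried H3K27ac (Fisher's exact test, adjusted p = 0.000246). Ezh2, the catalytic subunit of the complex, stood at a fold enrichment of 21.3 and 16.4, its partners Eed and Suz12 at 16.0 and 14.5 and at 15.3 and 9.90, and the demethylase gene Kdm6a at 26.2 and 18.5. The alternative catalytic subunit gene, Ezh1, stood at 11.2 and 8.01. H3K27me3 was found at 6 of the 20 genes, against 28.7% of the other genes (adjusted p = 1, exact test), and at 11 in replicate 1 taken alone. Among the 6 were Phf19, Ring1, Bmi1 and Cbx8, with the highest fold enrichment at Cbx8 (9.84 and 6.90).

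**Figure D1:**
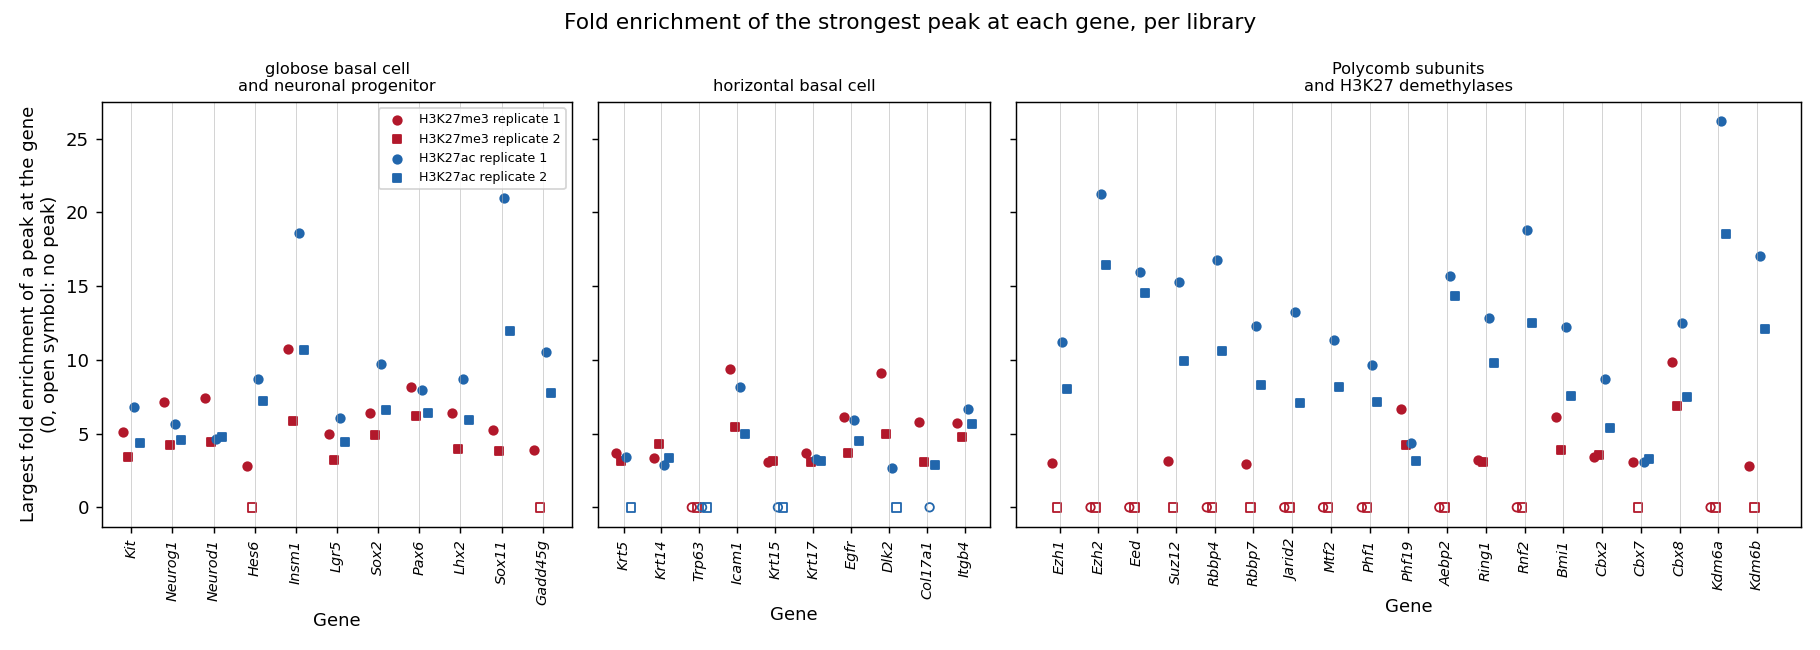
Largest fold enrichment (the authors' ratio, vertical axis) of a peak within 1 kb of either end of each gene (horizontal axis) shown from the globose basal cell, horizontal basal cell and Polycomb lists, with H3K27me3 in red and H3K27ac in blue, circles for replicate 1 and squares for replicate 2, and open symbols at 0 where a library had no peak. At Ezh2 only H3K27ac was found, at 21.3 and 16.4, whereas Neurog1 had peaks in all 4 libraries.

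Most of the listed genes of the GBC stage carried both marks. H3K27ac was found at 12 of 12 genes of the list of GBC and neuronal progenitor genes (Fisher's exact test, adjusted p = 0.0108), and H3K27me3 at 10 of them (adjusted p = 0.000372). Random lists of the same size, matched on gene length, had a median of 4 genes with H3K27me3, and 95% of them had 1 to 7. Among the 10 were Kit, Neurog1, Neurod1, Insm1, Lgr5, Sox2 and Pax6, while Hes6 and Gadd45g had an H3K27me3 peak in replicate 1 only. Sox2, Sox11, Pax6 and Lhx2 are also in the Sox, Pax and Lhx lists. Both marks were at 11 of 19 Sox, 20 of 44 Fox and 9 of 19 Wnt genes, but at 1 of 39 Hox and 1 of 14 Nkx genes. Whether the class of gene or the GBC stage gives the pair of marks was not tested. At Kit, the gene of the receptor used for the selection (chromosome 5, 75574987 to 75656722), fold enrichment was 5.11 and 3.41 for H3K27me3 and 6.80 and 4.39 for H3K27ac. At Neurog1, a regulator that drives progenitors toward neurons, it was 7.12 and 4.24 for H3K27me3 and 5.67 and 4.54 for H3K27ac. With peaks at a −log10 q of at least 5 only, 2 of the 12 genes carried H3K27me3, against 4.57% of the other genes (adjusted p = 0.177 by the exact test), while 8 of 12 did at a −log10 q of at least 2 (adjusted p = 0.000597, range over the alternatives 4.49e-05 to 0.177). At a −log10 q of at least 5, 7 of the 12 carried H3K27ac (adjusted p = 0.507, exact test, range 0.00207 to 0.507).

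Immature olfactory neuron genes had the same pair of marks. H3K27ac was at 10 of 10 (adjusted p = 0.0166) and H3K27me3 at 8 of 10 genes (adjusted p = 0.00269), by Fisher's exact test. Tubb3, Gng8, Stmn2 and Stmn4 were among the 8, and the neuronal tubulin gene Tubb3 stood at a fold enrichment of 5.14 and 3.66 for H3K27me3 and 9.28 and 6.23 for H3K27ac. Dcx, on the X chromosome, had no H3K27me3 peak. At a −log10 q of at least 5, 0 of the 10 genes carried H3K27me3 and 7 carried H3K27ac, with adjusted p-values of 1 and 0.317 by the exact test (ranges over the alternatives 9.16e-05 to 1 and 0.00755 to 0.317). The H3K27ac call also ended with 500 bp covered (0.289), in either replicate (0.0741) and over whole genes (0.0603), by the exact test. Among mature neuron genes, 7 of 14 carried H3K27me3 (adjusted p = 0.221) and 10 of 14 H3K27ac (adjusted p = 0.667), neither past the exact test, although H3K27me3 passed in 3 of 11 alternatives (0.00947 to 0.794). The odorant signalling gene Omp carried H3K27ac alone, at 6.18 and 4.18, and Gnal, the gene of the olfactory G protein, carried H3K27me3 alone, at 7.88 and 5.67.

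Across all 21883 protein-coding genes, 3828 (17.5%) carried both marks, 2447 (11.2%) H3K27me3 alone, 9482 (43.3%) H3K27ac alone and 6126 (28.0%) neither. The best-ranked genes with both marks were Ccdc106, Smg6, Insm1, Cracd, Ncoa5, Ldah, Msantd2 and Dock3. Insm1, a zinc finger regulator of neurogenic progenitors, stood at a fold enrichment of 10.8 and 5.83 for H3K27me3 and 18.6 and 10.7 for H3K27ac. H3K27me3 was found at 28.8% of genes with H3K27ac and 28.5% of genes without it (odds ratio 1.01, Fisher's exact test p = 0.736). Without the 1463 olfactory and vomeronasal receptor genes, most of which carried neither mark, the odds ratio was 0.820 (exact p = 4.46e-10). This direction was not stable either, since without those genes the odds ratio was 1.4 without H3K27me3 replicate 2 (exact p = 6.45e-36), 1.1 without H3K27ac replicate 2 (exact p = 0.00560), 1.88 in either replicate and 0.965 with windows of 2.5 kb (exact p = 0.264). The count of genes with both marks depended on the threshold: it was 1772 at a −log10 q of at least 2 and 111 at a −log10 q of at least 5, where the odds ratio was 0.139.

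Horizontal basal cells are the reserve stem cells that lie beneath the GBCs. Of 10 of their marker genes, 9 carried H3K27me3 (Fisher's exact test, adjusted p = 0.000278) and 5 H3K27ac (adjusted p = 0.622). The keratin gene Krt15 carried H3K27me3 alone, Krt5 also had an H3K27ac peak in replicate 1 only (3.44), and Icam1 carried both marks, with 9.36 and 5.42 for H3K27me3 and 8.17 and 4.96 for H3K27ac. Trp63, the master regulator of these cells, had no peak within 1 kb of either gene end in any library. Such windows miss a promoter inside the gene. Under an alternative that reaches further (windows of 2.5 kb or the whole gene), all 10 genes of the list, Trp63 included, carried H3K27me3. This does not place the mark at a promoter of Trp63. Of 53 keratin genes, 36 carried H3K27me3 (adjusted p = 1.81e-08) and 19 H3K27ac, which was below the share of other genes (adjusted p = 0.000866), by the exact test. Krt5 and Krt15 are in both the horizontal basal cell and the keratin list, so these lists are not independent. Of 10 microvillar and tuft cell genes, 7 carried H3K27me3 (adjusted p = 0.0166, exact test), among them Foxi1, Cftr, Trpm5 and Chat, and 6 carried H3K27ac (adjusted p = 1). The H3K27me3 calls of these 3 lists ended at a −log10 q of at least 2, with 4 of 10, 11 of 53 and 3 of 10 genes and adjusted p-values of 0.134, 0.587 and 0.518 by the exact test. Over the alternatives these exact tests ranged from 9.94e-05 to 0.494 for the horizontal basal cell genes, from 1.17e-08 to 0.587 for the keratins and from 0.00148 to 0.518 for the microvillar and tuft cell genes, whose call also ended with 500 bp covered (0.332).

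Markers of the other cell types that the selection could hold were tested in the same way. With windows of 1 kb and peaks in both libraries, none passed for either mark. The smallest adjusted p by Fisher's exact test was then 0.0650, but some alternatives passed. H3K27me3 and H3K27ac were found at 4 and 8 of 10 sustentacular cell genes, 4 and 3 of 6 Bowman's gland genes, 5 and 7 of 12 respiratory epithelium genes, 7 and 6 of 12 stroma and endothelium genes, and 3 and 3 of 6 olfactory ensheathing glia genes. H3K27me3 passed the exact test for the stroma and endothelium list in 6 of 11 alternatives (adjusted p 0.00409 to 0.369) and for the Bowman's gland list in 5 (0.00848 to 0.345), and in 1 alternative each H3K27ac passed as high for the sustentacular list (10 of 10 with windows of 2.5 kb) and as low for the stroma and endothelium list (1 of 12 at a −log10 q of at least 5). Mast cells and melanocytes also bear c-Kit. Of 9 mast cell genes, 3 carried H3K27me3 and 2, Hdc and Gata2, carried H3K27ac (adjusted p = 0.756 and 0.0650, exact test). This low H3K27ac share at mast cell genes passed the exact test in 5 of 11 alternatives (adjusted p 0.0156 to 0.157). Of 6 melanocyte genes 1 carried H3K27me3 and 2, Mitf and Pmel, carried H3K27ac. Of 12 leukocyte genes, 6 carried H3K27me3 and 9 H3K27ac (adjusted p = 0.195 and 0.482, exact test), against 60.8% of other genes with H3K27ac. Cd68 and Cd79a carried H3K27ac alone, and Csf1r and Lyz2 carried both marks. Ptprc had no peak in any library, and Itgam had an H3K27ac peak in replicate 1 only. Of 7 genes for cyclin-dependent kinase inhibitors, 4 carried H3K27me3 and 5 H3K27ac (adjusted p = 0.190 and 0.756, exact test). Their H3K27me3 share passed the exact test in 1 of 11 alternatives (adjusted p 0.0373 to 0.837). Cdkn2a and Cdkn2b, which restrain division and are classical Polycomb targets, carried both marks, with H3K27me3 at 12.3 and 8.04 over Cdkn2a.

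**Figure D2:**
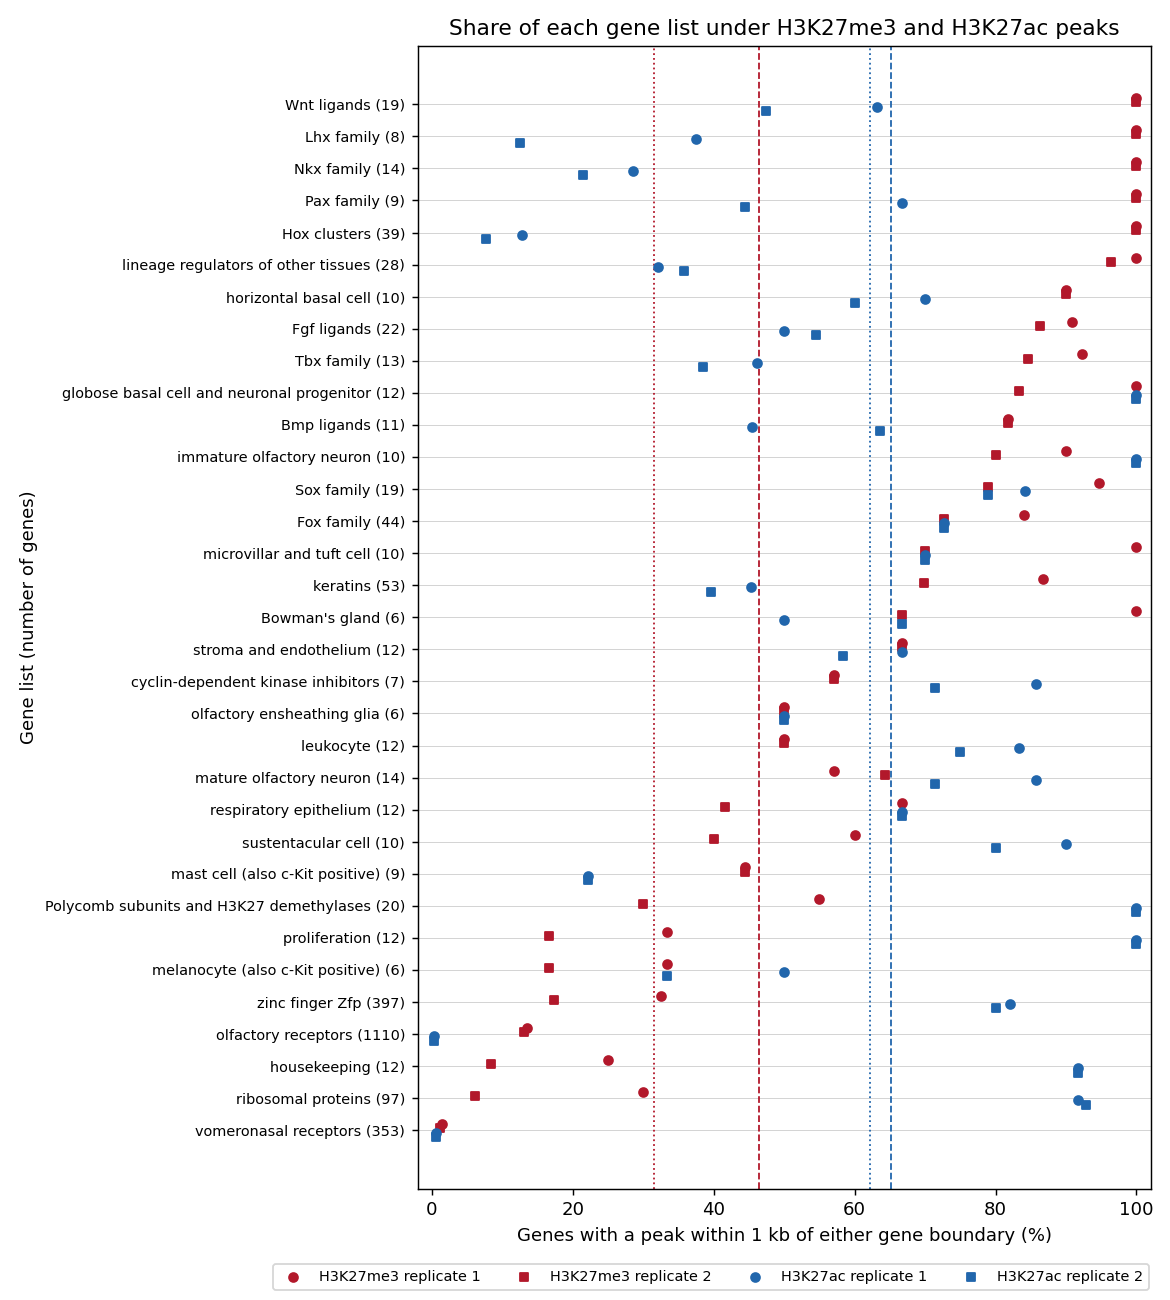
Share of the genes of each list (rows, with the number of genes) that had a peak within 1 kb of either gene end in each library, in percent, with H3K27me3 in red and H3K27ac in blue, circles for replicate 1 and squares for replicate 2, and vertical lines for all 21883 genes (dashed for replicate 1, dotted for replicate 2). All 39 Hox genes had H3K27me3 peaks in both libraries, and olfactory and vomeronasal receptor genes lay near 0% for H3K27ac.

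Receptor genes of the olfactory and vomeronasal systems carried almost no H3K27ac, and they carried H3K27me3 less often than other genes. Mappability was not analysed here, so a missing mark cannot be told apart from a shortage of reads placed at these genes. Of 1110 olfactory receptor genes, each of which is chosen by few neurons, 2 carried H3K27ac (Olfr750 and Olfr1033) and 99 carried H3K27me3 (8.92% against 29.7% of other genes, adjusted p = 5.48e-60, Fisher's exact test). Replicates 1 and 2 taken alone had H3K27me3 peaks at 150 and 145 of these genes, and no olfactory receptor gene carried the mark at a −log10 q of at least 5, while the share stayed below that of other genes in all alternatives. Of 353 vomeronasal receptor genes, 2 carried H3K27ac (adjusted p = 1.31e-139) and 1 carried H3K27me3 (adjusted p = 1.53e-49), by the exact test. The H3K27me3-marked olfactory receptor genes were unevenly spread over the chromosomes, with 9 of 9 on chromosome 15, 33 of 83 on chromosome 11 and 10 of 27 on chromosome 1, against 3 of 287 on chromosome 2 and 0 of 130 on chromosome 9 (8 and 3 in replicate 1 alone). This spread was not tested. On chromosome 1, Olfr1416, Olfr1415, Olfr1414 and Olfr1413 carried it, with fold enrichment of 3.63 and 3.56 at Olfr1416 and 4.17 and 3.24 at Olfr1414.

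The longest regions of the marks, merged across gaps of up to 3 kb for H3K27me3 and 12 kb for H3K27ac, were compared by span, without a test. H3K27me3 formed 26125 merged regions, of which 1708 spanned at least 10 kb. The longest covered Unc5a and Hk3 on chromosome 13 (54833906 to 55016138, 182 kb), followed by Cdh22 on chromosome 2 (165133107 to 165275796, 143 kb) and the Hoxb cluster on chromosome 11 (96226816 to 96360280, 133 kb, with Hoxb9, Hoxb8, Hoxb7 and Hoxb6 among its 8 genes). The fourth, on chromosome 8 (120792728 to 120920810), held no end of a protein-coding gene. Pax2, Ttc34, Grik3, Foxc2 with Foxl1, the Hoxc cluster and Adra2c followed. H3K27ac formed 20574 stitched regions, of which 5382 spanned at least 10 kb. The longest lay over Msi2, which encodes an RNA-binding protein of progenitor cells, on chromosome 11 (88354679 to 88728303, 374 kb, of which 211 kb were covered in both libraries), followed by a region with Glod4, Mrm3, Nxn and Timm22 (268 kb, 80.6 kb covered) and by Cmip with Plcg2 (258 kb, 88.8 kb covered). Further regions lay over Klhl26 and Tmem59l, over Eya2 with Zmynd8, over Tns3, Irf2bp2, Tmem189 with Cebpb and Zmiz1, and over Tmem259, Cnn2, Abca7 and Arhgap45. The number of long H3K27me3 regions ranged from 454 to 3322 with merging gaps of 1 kb and 10 kb, and 3 and 5 of the 10 longest remained among the 10 longest. Without H3K27me3 replicate 1 or 2 the number was 2750 or 3385.

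**Figure D3:**
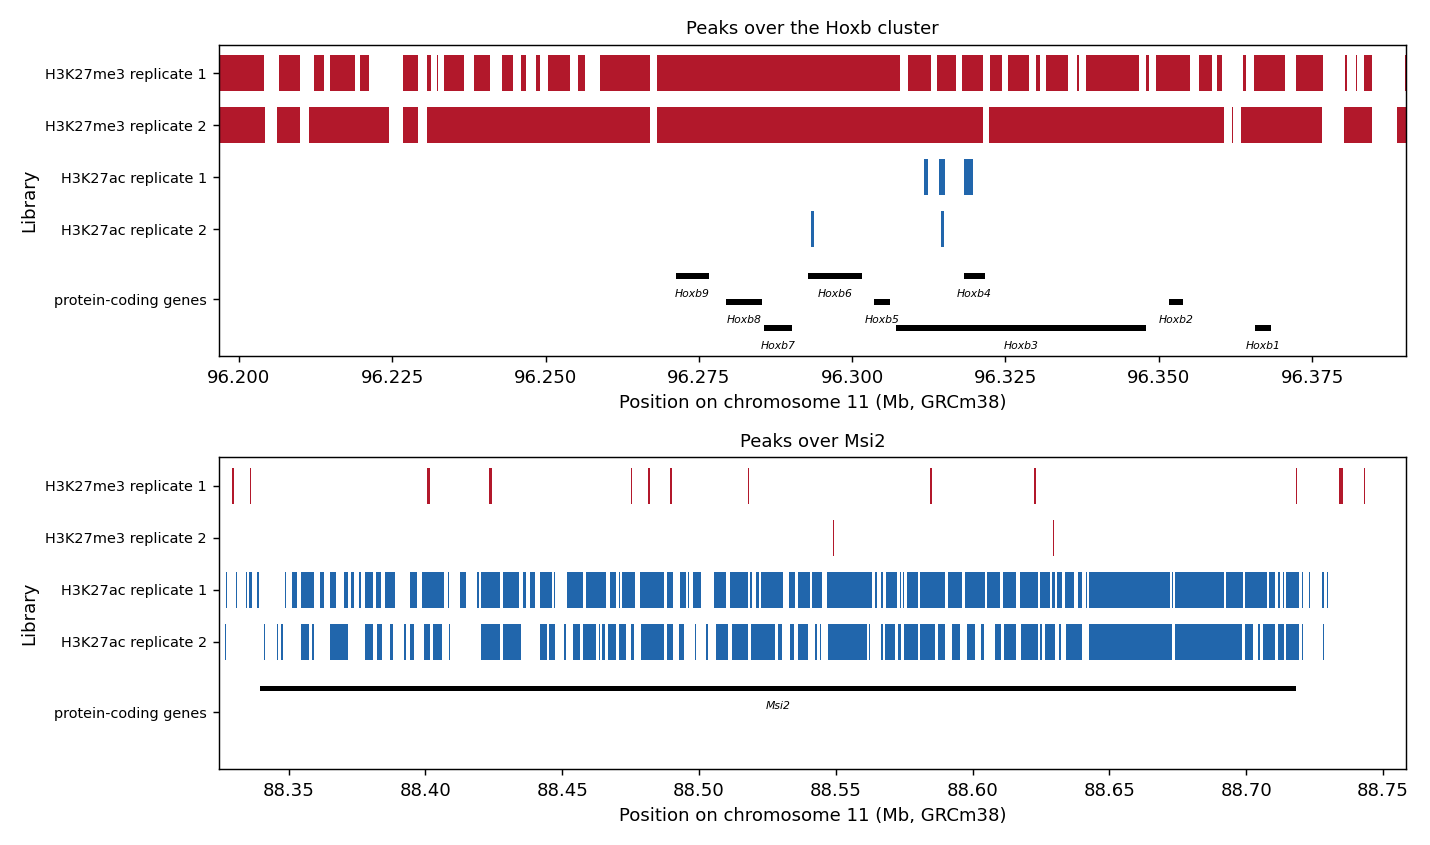
Peaks of the 4 libraries (rows, H3K27me3 in red and H3K27ac in blue) and protein-coding genes (black bars) along chromosome 11 in Mb of GRCm38, over the Hoxb cluster (upper panel) and over Msi2 (lower panel), each with 30 kb on both sides. H3K27me3 covers most of the 133 kb Hoxb region in both replicates, and H3K27ac peaks of both replicates cover 211 kb of the 374 kb Msi2 region.

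At gene boundaries both marks were denser than random placement gives, H3K27ac more so. Consensus H3K27ac regions had 24.2% of their length within 1 kb of a gene end, 53.4% in gene bodies and 22.4% between genes, against 3.26%, 39.2% and 57.5% in rotated lists. Consensus H3K27me3 regions had 14.7% at gene ends and 43.3% in gene bodies, against 3.27% and 39.6%, and the rest between genes. The excess at boundaries was 7.43 times for H3K27ac and 4.48 times for H3K27me3, each with a permutation p of 0.005, the smallest that 200 rotations can give. In single libraries it was 5.55 and 6.35 times for H3K27ac and 3.66 and 3.16 times for H3K27me3.

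Replicates shared far more sequence than the marks did. The H3K27ac libraries shared 65.5 Mb (Jaccard index 0.498), 15.7 times the length in rotated lists, and 60.1% of replicate 1 peaks and 75.4% of replicate 2 peaks overlapped a peak of the other. The H3K27me3 libraries shared 50.6 Mb (Jaccard index 0.359), 12 times the rotated length, and 42.1% of replicate 1 peaks and 57.0% of replicate 2 peaks overlapped a peak of the other. Consensus regions of the 2 marks shared 5.83 Mb, which was 11.5% of the H3K27me3 and 8.89% of the H3K27ac length. Rotated lists shared 1.48 ± 0.165 Mb (SD over 1000 rotations), and no rotation exceeded 2.08 Mb, so the overlap was 3.95 times that of random placement (permutation p = 0.002, two-sided, the smallest possible). Rotation does not keep gene density, and both marks were enriched at gene ends, 4.48 times for H3K27me3 and 7.43 times for H3K27ac. An overlap above random placement therefore does not show that the marks coincide beyond their common place near genes. Across genes their odds ratio was 1.01 (Fisher's exact test p = 0.736), with a direction that changed among the alternatives. For pairs of libraries the ratio was 4.00 and 3.93 for H3K27me3 replicate 1 with H3K27ac replicates 1 and 2, and 2.71 and 2.61 for H3K27me3 replicate 2. At a −log10 q of at least 5 the consensus ratio was 2.19.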

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

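The shared-input test was chosen only after its result was seen, and the other tests of explanations were written after the data were in hand but before their own results. In 7 gene lists H3K27me3 and H3K27ac were both called, in opposite directions, and this is what put them here. The difference was also tested by Fisher's exact test on genes with exactly 1 mark, which is no independent evidence, since the lists were chosen by the calls themselves. Other lists passed that exact test too, among them the Wnt ligands (adjusted p = 5.36e-07), the Fgf ligands (2.33e-06) and the olfactory receptors (1.69e-64). Over all genes 28.7% carried H3K27me3 and 60.8% H3K27ac, so a difference near -32 percentage points is the value without a change. The share with H3K27me3 minus the share with H3K27ac was, by this exact test, 97.4 percentage points for the Hox clusters (adjusted p = 9.44e-26), 92.9 for the Nkx family (6.11e-09), 87.5 for the Lhx family (5.01e-05), 67.9 for the lineage regulators of other tissues (8.83e-13) and 32.1 for the keratins (1.53e-10). It was -85.6 for the ribosomal protein pattern (4.17e-08) and -64.5 for the Zfp zinc finger genes (2.91e-10). All 7 were seen in libraries of 2 replicates per mark, and genes of a cluster share peaks.

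Genes with both marks were the first pattern weighed. If the marks had lain at opposite ends of a gene, few genes would have had them on common sequence, but in 82.4% of genes with both marks the consensus regions shared a base inside 1 boundary window. If strongly acetylated, open chromatin were recovered by any antibody, H3K27me3 would have become more frequent with H3K27ac strength. It became rarer: 3.16% of acetylated genes carried it in the top 10% by H3K27ac fold and 66.5% in the bottom 10%, a difference of -63.3 percentage points. The shared sequence argues against opposite ends as the source for most of these genes. The second test cannot exclude a background part, because marks that avoid each other would also make H3K27me3 rarer at strongly acetylated genes. A candidate explanation, not tested here, is that a part of progenitor and immature neuron genes keeps Polycomb methylation beside acetylation. At a −log10 q of at least 5, however, genes with both marks fell from 3828 to 111. H3K27me3 was then left at 2 of 12 progenitor and 0 of 10 immature neuron genes. The lists come from pools of cells, so whether both marks sat in the same cells or in different cells of the selection was not tested, and this stays open.

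H3K27me3 replicate 1 shared more of its length with H3K27ac than replicate 2 did, 17.2% against 11.6%, a ratio of 1.49. The input that H3K27me3 replicate 1 shares with H3K27ac replicate 2 would have raised the overlap with that library most, but the length shared by H3K27me3 replicate 1 relative to replicate 2 was only 1.009 times as large with H3K27ac replicate 2 as with replicate 1. Replicate 1 also had more peaks. With only its best peaks, as many as replicate 2 held, 16.3% of its length lay under H3K27ac, still 1.411 times the share of replicate 2, which argues against peak number as the whole cause. No biological explanation was tested, since the labels give no difference between the pools, and differences in antibody background or depth stay open.

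The X chromosome was sparsely covered in every library, at 1.07% and 0.673% for H3K27me3 and 0.542% and 0.477% for H3K27ac, against 4.08%, 3.68%, 4.53% and 3.51% of the autosomes. Fewer genes do not account for all of it. With chemosensory receptors left out, 37.9% of 959 X genes carried H3K27ac against 67.4% of 19205 autosomal genes, a ratio of 0.562. For H3K27me3 these shares were 21.0% and 31.1%, a ratio of 0.674. The ratios of coverage were lower, at 0.120 to 0.262, so fewer genes may account for a part. Fewer reads from a chromosome present once in males would leave only its stronger peaks. The median fold of X peaks was 1.39 and 1.21 times the autosomal one for H3K27ac but 1.00 and 0.986 times for H3K27me3, so a shortage of reads cannot be told apart from a lower density of marks. Reads and input on the X chromosome were not analysed here.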

How the results depend on the processing

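The −log10 q threshold of 2, the whole-gene windows, the shared-base count and the set without receptor genes were chosen after seeing the data. Replicate overlaps, the overlap of the marks and the excess at gene boundaries kept their direction and stayed past the threshold under every alternative run. The marks shared 2.19 to 4.36 times the rotated length. The association of the marks across genes did not hold: its odds ratio fell from 1.01 to 0.139 at a −log10 q of at least 5, 0.633 at 2, 0.922 with windows of 500 bp, 0.869 with 500 bp covered and 0.820 without receptor genes. It was 1.22 with windows of 2.5 kb, 1.4 over whole genes, 2.36 in either replicate and 0.956 to 1.82 when a library was left out, the lowest without H3K27me3 replicate 1 and the highest without H3K27me3 replicate 2. Genes with both marks numbered 111 at a −log10 q of at least 5, 1772 at 2, 8215 in either replicate, 6125 over whole genes and 3989 to 6956 without a library, the highest without H3K27me3 replicate 2. Genes with H3K27me3 alone numbered 891 at a −log10 q of at least 5. Fewer peaks remain at a stricter threshold by construction, and the cause was not tested further.

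Regions of at least 10 kb numbered 4660 (H3K27me3) and 8197 (H3K27ac) in either replicate, 3322 and 454 for H3K27me3 with gaps of 10 kb and 1 kb, and 2750 to 3385 with 1 of the H3K27me3 libraries left out (2750 without replicate 1 and 3385 without replicate 2). At a −log10 q of at least 5 the H3K27me3 excess turned to -4.58 percentage points for immature neuron genes and -4.59 for keratins. Of the 33 calls on lists, 23 remained at a −log10 q of at least 5, 30 at 2, 30 with 500 bp covered, 29 in either replicate and 32 over whole genes, while 6, 7, 2, 2 and 5 others were gained. All 33 remained with windows of 500 bp and 2.5 kb and without H3K27me3 replicate 1 or H3K27ac replicate 1, with 2, 4, 2 and 0 others gained. Without H3K27me3 replicate 2 the Bmp ligand call was lost (adjusted p = 0.0579, exact test), and without H3K27ac replicate 2 the Lhx call (0.220), with 1 other gained in each. The alternative at annotated transcript starts was not run, because transcript starts were not used here. No paired analysis was possible because the labels do not say which libraries came from the same pool of mice, and peak lists were compared by overlap. The unknown depth limits every count of peaks.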

Other observations

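The groups in this part were chosen after their values were seen, among 375 groups of at least 10 genes that share the first 3 letters of their symbol, with Fisher's exact test adjusted over those groups and both marks. H3K27me3 was more frequent than in other genes in 64 groups and less frequent in 42, and H3K27ac in 100 and 49, so the groups named here are examples and not a test of a theme. Of 94 Kcn genes, which encode potassium channels, 74 carried H3K27me3 (adjusted p = 1.23e-21, exact test), as did 20 of 24 Gri genes, mostly for glutamate receptor subunits (adjusted p = 8.36e-07), and 16 of 18 Htr genes, mostly for serotonin receptors (adjusted p = 3.08e-06). At Kcnc2 the fold enrichment was 11.4 and 8.50, and at Grin3a it was 11.1 and 6.42. These 3 groups still passed the exact test at a −log10 q of at least 5, with 19 of 94, 9 of 24 and 7 of 18 genes (adjusted p = 9.53e-07, 1.12e-05 and 0.000126). H3K27me3 was also found at 25 of 31 Cac genes (adjusted p = 7.35e-08) and 13 of 18 Scn genes (adjusted p = 0.00122), mostly for calcium and sodium channels, by the exact test. The Cac call ended at a −log10 q of at least 5 (2 of 31, adjusted p = 0.951, exact test). The Scn call ended at a −log10 q of at least 5 (0.929) and 2 (0.220), without H3K27me3 replicate 2 (0.0864) and in either replicate (0.0583), all by the exact test. Related groups did not pass for H3K27me3: 13 of 30 Gab genes, mostly for GABA receptors (adjusted p = 0.192), 3 of 10 Glr genes (adjusted p = 1) and 4 of 18 Clc genes (adjusted p = 0.885), by the exact test.

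Some groups of genes that most cells use carried H3K27ac. It was at 75 of 78 Mrp genes, mostly for mitochondrial ribosomal proteins, 47 of 49 Ndu genes, mostly for respiratory complex I, 54 of 56 Eif genes for translation factors, 47 of 51 Psm genes for the proteasome and 35 of 35 Vps genes for vesicle sorting. The adjusted p-values by Fisher's exact test were 2.02e-11, 5.17e-07, 2.60e-08, 1.27e-05 and 8.95e-07, and these calls remained under all alternatives. The mitochondrial Cox group (21 of 27, adjusted p = 0.160) and the Fbx group of ubiquitin ligase genes (55 of 78, adjusted p = 0.165) did not pass the exact test for H3K27ac. H3K27me3 was at 3, 2, 4, 5 and 1 of the Mrp, Ndu, Eif, Psm and Vps genes in both libraries, but at 21, 13, 18, 18 and 7 without H3K27me3 replicate 2. There the Eif and Psm shares, 32.1% and 35.3%, were still below the 46.5% of other genes, but the calls ended (adjusted p = 0.0838 and 0.227, exact test). At a −log10 q of at least 5 no H3K27me3 call on these 5 groups remained, at 2 those on the Psm and Vps genes ended (0.195 and 0.0705), and in either replicate those on the Eif, Psm and Vps genes ended (0.0661, 0.113 and 0.0570), by the exact test. The kallikrein genes (Klk), a cluster on chromosome 7, carried H3K27me3 at 17 of 27 genes (adjusted p = 0.00219) and H3K27ac at 1 (adjusted p = 1.41e-08) by the exact test. The H3K27me3 call on the Klk genes ended with peaks at a −log10 q of at least 2 (6 of 27, adjusted p = 0.583) and 5 (0 of 27, 0.940), with windows of 500 bp (11 of 27, 0.157) and with 500 bp covered (10 of 27, 0.206), by the exact test.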
